A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

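RNA abundance was measured on Affymetrix Yeast Genome S98 GeneChip arrays in 12 steady-state chemostat cultures of the Saccharomyces cerevisiae laboratory strain CEN.PK113-7D, 1 array per culture. The growth-limiting carbon source was glucose, maltose, ethanol or acetate, with 3 numbered cultures each, all aerobic at a dilution rate of 0.1 per hour, 30 °C and pH 5. The deposited values are linear probe set intensities (signals) scaled by the authors, and all 12 arrays had the same 2% trimmed mean. Per the labels, MAS5 made the signals of the maltose, ethanol and acetate arrays; its version is not given in the sources used here. The software behind the 3 glucose arrays is not given in the sources used here either. These 3 arrays come from older records of the same laboratory with their own protocol text, so record age cannot be separated from glucose. The array descriptions carry a code letter, P on 9 arrays, M on maltose arrays 1 and 2, and V on glucose array 2. Arrays have no read depth: their number and the signal over background limit the precision.

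Of 9335 probe sets, 60 controls were left out. Among the other 9275, the platform annotation and the reference gene table gave 1 gene for 6504 probe sets, several genes for 328 and none for 2443. Signals were rescaled to a common 2% trimmed mean, floored at 12 and log2 transformed. Probe sets above 12 on at least 3 of the 12 arrays were tested, 7176 in all, which covered 5325 genes; 2099 dim probe sets were left out. Probe sets without a gene name stayed in the tests and in the counts. Near-identical genes, such as HXT6 with HXT7, the maltase genes of the MAL1x and MAL3x loci, the IMA isomaltases, ADH1 with ADH2, and the TDH genes, are open to cross-hybridisation. MAL12 was present only on a probe set shared by several genes and could not be tested alone. No genome build was part of the sources used here, so no coordinates are given.

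A model with 1 mean per carbon source was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend). Contrasts were the mean of ethanol and acetate against the mean of glucose and maltose, and the 6 pairs of sources; a moderated F test covered all 4 sources. Benjamini-Hochberg adjustment was applied within each contrast, and an adjusted p under 0.05 made a call. A probe set was specific to a source when it passed in the same direction against each of the other 3 sources. The sign of calls was compared between contrasts that share no array. The p-values measure the spread between cultures grown with the same carbon source. The replicate numbers were used only in an alternative.

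Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the first set of alternatives. The 23 lists were glycolysis, gluconeogenesis and glyoxylate cycle, ethanol and acetate metabolism, pyruvate metabolism, TCA cycle, pentose phosphate pathway, respiratory chain and ATP synthase, hexose transporters and sensors, maltose utilisation, galactose and sucrose utilisation, carnitine shuttle and carboxylate transport, beta-oxidation, peroxisome biogenesis, carbon regulators, trehalose and glycogen, heat shock and general stress, weak acid response, cytosolic ribosomal proteins, oxygen limitation markers, phosphate limitation markers, nitrogen limitation markers, early meiosis and mating type. The probe set with the highest mean signal stood for a gene. Each list was tested in 7 contrasts with limma's fry, whose directional p asks whether the genes of a list moved one way on balance, with adjustment over all 161 tests. The lists were tested again with camera, with an estimated and with a preset correlation between genes of 0.01. For each list the members were also counted with p adjusted over the list alone.

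The rule for named genes took, per contrast, the 8 highest and 8 lowest log2 changes among called single-gene probe sets whose groups did not overlap. It added up to 4 called members of each list, or 2 values where none passed, and the 5 largest source-specific changes per direction. ADH2, ACS1, ICL1, MLS1, FBP1, PCK1, JEN1, MAL11, MAL12, HXT7, HXT5, CAT8, SIP4, HXK1 and HXK2 were always taken where testable. Members of lists that are only summarised may be left out of the text.

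The pipeline was tested on simulated data with 12 arrays and 7176 probe sets. Changes were planted only in probe sets above a minimum mean signal. The noise was independent, with no difference in RNA quality between arrays and no shift of whole arrays. The recovery rates do not cover dim probe sets or such effects. For the contrast of ethanol and acetate with the sugars it recovered 34.3% of genes changed 1.50-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold, with 12 false calls among 157. For maltose against glucose it recovered 8.96%, 50.7% and 97.0%, with 8 false calls among 112. None of 50 lists without a change had a fry p under 0.05 in a simulation with independent genes. A list with a built-in shift was found in both contrasts.

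Alternatives covered the scaling (signals as deposited, quantile normalization), the floor (50, or a pseudocount of 16), the filter (none, or a mean signal of at least 100), the variance model, array weights, a fold minimum of 2, the replicate number as a block, the code letter as a block, only arrays with code letter P, leaving out each array in turn, only the arrays compared, and the list test. The other letters occur only on some maltose and glucose arrays. With the letter as a block the changes are therefore the same as with only code letter P. The settings differ in the estimate of the spread alone and are not separate checks. Chosen after seeing the data were 5 more: only array 1 of ethanol and of acetate, the same without maltose array 2, the mean log2 3'/5' signal ratio of the actin and YER148W controls as a covariate, leaving out glucose arrays 1 and 3, and leaving out probe sets above 2000. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.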

Results

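The series compares the transcriptome of yeast whose growth was limited by glucose, maltose, ethanol or acetate at 1 growth rate, to ask how far transcription sets the use of central carbon metabolism. Each source had 3 cultures, each on its own array. Median signals lay between 41.7 and 48.4 on 11 arrays and at 22.8 on maltose array 2. Pearson's r of log2 signals across probe sets, which are not independent replicates, ran from 0.941 to 0.982 within sources and from 0.905 to 0.982 between them. The signal ratio of the 3' to the 5' actin control probe set, a sign of RNA quality, was 9.27 and 13.98 on ethanol arrays 2 and 3 and 10.2 and 13.1 on acetate arrays 2 and 3. It was 3.31 or less on the other 8 arrays. The 3'/5' ratio used as a covariate was the mean log2 ratio of actin and YER148W, another control gene.

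Growth on the C2 compounds ethanol and acetate came with high transcripts for making sugar phosphates and C4 acids. The question was which genes separate C2 from sugar metabolism. PCK1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose 19.1-fold (log2 4.25 ± 0.16, SE, 6 arrays against 6, limma adjusted p = 9.39e-11). Its mean signal was 3599 ± 587 (SD, n = 3) in ethanol and 3474 ± 563 in acetate cultures, against 202 ± 28.2 in glucose and 173 ± 47.4 in maltose cultures. FBP1, encoding fructose-1,6-bisphosphatase, rose 10.2-fold (log2 3.34 ± 0.16), and the malate synthase gene MLS1 rose 9.04-fold (log2 3.18 ± 0.18). ICL1, encoding isocitrate lyase of the glyoxylate cycle, rose 4.87-fold (log2 2.28 ± 0.14). All 7 measured genes of gluconeogenesis and the glyoxylate cycle rose (7 adjusted over the list alone, fry adjusted p = 9.59e-07, and adjusted p = 0.0218 with an estimated correlation). Of these 7 genes, 6 passed with only array 1 of ethanol and of acetate, which had the low actin ratios, and 7 with the mean 3'/5' ratio of actin and YER148W as a covariate.

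**Figure D1:**
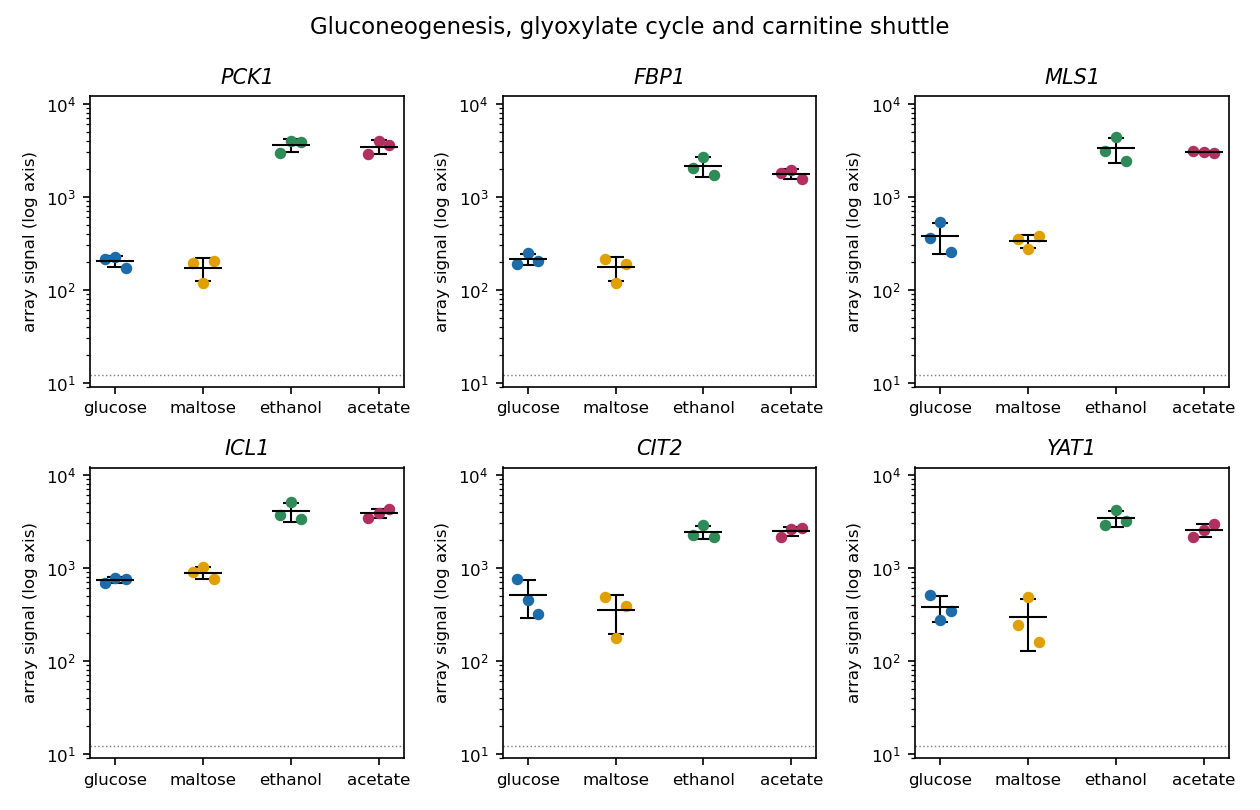
Array signals (log axis) of PCK1, FBP1, MLS1, ICL1, CIT2 and YAT1 for the 4 carbon sources; points are the 3 arrays, lines the mean and SD, and the dotted line the floor of 12. For all 6 genes each ethanol and acetate array lies above each glucose and maltose array.

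Genes that move C2 units and C4 acids rose with them. YAT1, an outer mitochondrial carnitine acetyltransferase gene, rose 9.40-fold (log2 3.23 ± 0.23), CRC1, the mitochondrial carnitine carrier gene, rose 6.22-fold (log2 2.64 ± 0.15), and the acetyltransferase genes YAT2 and CAT2 rose 2.98-fold and 2.99-fold. In the carnitine shuttle and carboxylate transport list, 8 of 12 genes rose and 2 fell (8 and 3 adjusted over the list alone, fry adjusted p = 3.27e-06, and adjusted p = 0.0512 with an estimated correlation). JEN1, the lactate and pyruvate permease gene, was among those that fell (log2 -0.83 ± 0.13). In the TCA cycle list 13 of 17 genes rose and 0 fell at an adjusted p under 0.05 (13 and 0 adjusted over the list alone, fry adjusted p = 2.31e-05, and adjusted p = 0.0587 with an estimated correlation). SDH1, a succinate dehydrogenase gene, rose 2.22-fold, and the isocitrate dehydrogenase genes IDH1 and IDH2 rose 2.04-fold and 1.86-fold. CIT2, the peroxisomal citrate synthase gene, rose 6.20-fold (log2 2.63 ± 0.24). With only array 1 of ethanol and of acetate, 2 arrays in place of 6, 3 TCA cycle and 5 carnitine and transport genes passed, and the list medians of log2 0.63 and 0.94 became 0.66 and 0.97 (0.65 and 1.07 with the 3'/5' ratio as a covariate).

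Smaller changes marked respiration and pyruvate use. The pyruvate carboxylase gene PYC1 rose 2.03-fold, and 3 of 8 pyruvate metabolism genes rose (5 adjusted over the list alone, fry adjusted p = 0.00286, and adjusted p = 0.271 with an estimated correlation). NDE2, an external NADH dehydrogenase gene, rose 3.46-fold (log2 1.79 ± 0.15), while CYC7, the minor cytochrome c gene, was at least 6.03-fold lower, since all acetate arrays were at the floor. In the respiratory chain and ATP synthase list 9 of 33 genes rose and 2 fell (14 and 3 adjusted over the list alone, fry adjusted p = 0.00493, and adjusted p = 0.43 with an estimated correlation). Neither list passed by fry with only array 1 of ethanol and of acetate or with the 3'/5' ratio as a covariate (adjusted p up to 0.230 and 0.252 over the alternatives). By limma the pyruvate list then had 0 genes up with array 1, and 0 up and 1 down with the covariate (median log2 0.43 became 0.27 and 0.25). The respiratory list had 1 up and 1 down in both settings (0.26 became 0.22 and 0.20). ACS1, encoding the acetyl-CoA synthetase of derepressed cells, rose 1.89-fold (log2 0.92 ± 0.14), with no call when only array 1 of ethanol and of acetate was kept (log2 0.80) or the 3'/5' ratio entered the model (log2 0.71). ADH2, the ethanol-oxidising alcohol dehydrogenase gene, rose 1.55-fold (log2 0.63 ± 0.20, adjusted p = 0.0431). ADH2 differed from glucose cultures (log2 1.13 ± 0.29 on ethanol, limma adjusted p = 0.048, and 1.10 ± 0.29 on acetate, adjusted p = 0.0342). It had no called difference from maltose (0.16 ± 0.29, limma adjusted p = 0.759, and 0.13 ± 0.29, adjusted p = 0.788). Maltose cultures read above glucose by a like step that was not called (log2 0.97 ± 0.29, limma adjusted p = 0.244). Whether low readings of the glucose arrays add to these differences stays open. The alternative without glucose arrays 1 and 3 leaves 1 glucose array and cannot decide it. The C2 call of ADH2 ended on leaving out any of 7 single arrays (ethanol 2 or 3, acetate 2 or 3, maltose 3, glucose 1 or 3), with adjusted p between 0.0607 and 0.114. The ethanol and acetate metabolism list had 3 genes up and 3 down of 15 (3 and 4 adjusted over the list alone, fry adjusted p = 0.914); its median of -0.04 and mean of -0.03 were negative and the test's direction was up.

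The transcription factor gene SIP4, an activator of gluconeogenic genes, rose 4.87-fold (log2 2.28 ± 0.22). ADR1, an activator of ADH2 and peroxisomal genes, rose 2.19-fold, with overlapping groups (limma adjusted p = 0.0133). Among the pairs of a C2 source with a sugar, ADR1 was called only for acetate against maltose (log2 1.75 ± 0.40, limma adjusted p = 0.0122). CAT8, the activator gene upstream of SIP4, did not pass (log2 0.49 ± 0.30, adjusted p = 0.267). Repressor genes of glucose signalling, MTH1 and MIG2, fell, MTH1 2.93-fold and MIG2 at least 2.04-fold, with all ethanol arrays at the floor for MIG2. Against glucose MIG2 was not called on ethanol or on acetate, and against maltose MTH1 was not called on ethanol. The 19 carbon regulators showed no common direction (5 up, 2 down, the same counts adjusted over the list alone, fry adjusted p = 0.607, median -0.05, mean 0.12). With the 3'/5' ratio as a covariate limma called 2 up and 1 down, and the list median was log2 0.35. With only array 1 of ethanol and of acetate the median was 0.09. REG2, a phosphatase subunit gene, rose 6.69-fold, and TPO2, a polyamine exporter gene, rose 7.65-fold.

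Genes of sugar uptake and phosphorylation fell. HXK1, encoding a hexokinase, fell 5.73-fold (log2 -2.52 ± 0.18), and TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, fell 3.08-fold. HXK2, the hexokinase gene of glucose-rich cells, was lower by a smaller step (log2 -0.56 ± 0.18, adjusted p = 0.046), a call that any of 9 single arrays ended when left out (ethanol or acetate 2 or 3, maltose 2 or 3, or any glucose array; adjusted p up to 0.132) and that no single pair of sources gave. Of 16 glycolysis genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, fry adjusted p = 0.00115, and adjusted p = 0.113 with an estimated correlation). The riser, TDH3, was called at a limma adjusted p of 0.0424 with overlapping groups. Its signals on glucose arrays 1 and 3 were 281 and 99.6 against 3910 on glucose array 2. Among 11 hexose transporters and sensors 5 fell and 1 rose (5 and 1 adjusted over the list alone, fry adjusted p = 0.0102, and adjusted p = 0.2 with an estimated correlation). The fry call of this list ended without glucose arrays 1 and 3, which leaves 1 glucose array, and without probe sets above 2000. HXT2 fell 2.33-fold and HXT7 fell 1.56-fold, and HXT5, a transporter gene of slow growth, rose 1.62-fold. HXT5 and HXT7 were called against glucose only, with values close to the threshold. The limma adjusted p was 0.0365 on ethanol and 0.0342 on acetate for HXT5, and 0.043 and 0.0437 for HXT7. Against maltose HXT5 was at log2 0.56 ± 0.22 on ethanol and 0.48 ± 0.22 on acetate (limma adjusted p = 0.126 and adjusted p = 0.154). HXT7 was at -0.56 ± 0.20 and -0.48 ± 0.20 (adjusted p = 0.0953 and adjusted p = 0.121). The pentose phosphate pathway had 7 of 10 genes down and 1 up (7 and 1 adjusted over the list alone, fry adjusted p = 0.000652, and adjusted p = 0.0512 with an estimated correlation): GND2, a 6-phosphogluconate dehydrogenase gene, fell 2.95-fold, and RKI1, a ribose-5-phosphate isomerase gene, rose 3.14-fold. With only array 1 of ethanol and of acetate 2 glycolysis genes, 1 pentose phosphate gene and 0 hexose transporters were called lower by limma. The medians of these lists went from log2 -0.47, -1.01 and -0.28 to -0.24, -0.75 and -0.19, and to -0.37, -0.70 and -0.10 with the covariate.

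Maltose genes fell, from high levels in maltose cultures. MAL11, an alpha-glucoside permease gene, fell 14.1-fold (log2 -3.81 ± 0.17) and MAL31, a maltose permease gene at another locus, fell 4.53-fold; 4 of 7 maltose utilisation genes fell and 0 rose at an adjusted p under 0.05 (4 and 1 adjusted over the list alone, fry adjusted p = 6.74e-06, and adjusted p = 0.0224 with an estimated correlation). In the galactose and sucrose list 4 of 7 genes rose and 1 fell (4 and 1 adjusted over the list alone, fry adjusted p = 0.0062, and adjusted p = 0.339 with an estimated correlation). GAL10 was at least 2.07-fold higher, with all maltose arrays at the floor, and SUC2, the invertase gene, fell 2.05-fold; among probe sets with a mean signal of at least 100 the direction of this list turned to down. The galactose and sucrose list lost its fry call after quantile normalization, with a floor of 50 and with the code letter as a block.

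Stress and acid-response genes were lower on C2 compounds. FDH1, a formate dehydrogenase gene, fell 30.4-fold on 1 of its 2 probe sets (log2 -4.92 ± 0.40) and 16.0-fold on the other, and PDR12, encoding an exporter of weak organic acids, fell 13.1-fold (log2 -3.72 ± 0.25). SPI1, a cell wall protein gene of the stress response, fell 5.87-fold. Heat shock and general stress genes fell in 8 of 13 cases and rose in 1 (10 and 1 adjusted over the list alone, fry adjusted p = 0.00114, and adjusted p = 0.111 with an estimated correlation). The riser, SSA1, was called at a limma adjusted p of 0.0391 with overlapping groups. It read 0.0 and 98.1 on glucose arrays 1 and 3. Weak acid response genes fell in 4 of 7 cases and rose in 1, TPO2 (5 and 1 adjusted over the list alone, fry adjusted p = 0.00115, and adjusted p = 0.0617 with an estimated correlation). With only array 1 of ethanol and of acetate 4 heat shock and 2 weak acid genes were called lower; the medians of log2 -0.84 and -1.04 became -0.82 and -0.77, and -0.90 and -0.88 with the covariate. YJR115W, YEF1 (a NAD kinase gene) and YPR145C-A fell 9.30-fold, 6.62-fold and 6.71-fold.

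Nitrogen scavenging genes rose in 7 of 13 cases (7 adjusted over the list alone, fry adjusted p = 0.00891, and adjusted p = 0.303 with an estimated correlation), among them DUR3, a urea and polyamine permease gene, 2.69-fold, the ammonium permease gene MEP2, 2.60-fold, and the allantoicase gene DAL2, 2.47-fold; limma called 0 of the 13 with only array 1 of ethanol and of acetate and 3 with the 3'/5' covariate, while the list median of log2 0.53 became 0.61 and 0.64. The list lost its fry call with the code letter as a block, among arrays with code letter P, without glucose arrays 1 and 3, and with only array 1 (adjusted p up to 0.159 over the alternatives). Early meiosis genes rose in 1 of 4 cases, SPS4 (1 adjusted over the list alone, fry adjusted p = 0.00995, and adjusted p = 0.433 with an estimated correlation). That call ended with a floor of 50, with the letter as a block and among arrays with code letter P. Of the 14 lists that passed by fry in this contrast, 4 still passed with only array 1 of ethanol and of acetate (gluconeogenesis and glyoxylate, TCA cycle, carnitine shuttle and maltose utilisation). With the covariate 9 did; pyruvate metabolism, the respiratory chain, hexose transporters, galactose and sucrose, and early meiosis were lost in both settings. The remaining 9 lists did not pass. Beta-oxidation had 0 of 13 genes called by limma, also adjusted over the list alone (fry adjusted p = 0.652; CTA1 log2 0.36 ± 0.13, FOX2 log2 0.33 ± 0.16). Peroxisome biogenesis had 2 of 17 up (4 adjusted over the list alone, fry adjusted p = 0.0658), trehalose and glycogen 3 of 17 down (3 adjusted over the list alone, fry adjusted p = 0.126), and cytosolic ribosomal proteins 2 up and 13 down of 81 (3 and 17 adjusted over the list alone, fry adjusted p = 0.495). Oxygen limitation markers had 1 of 9 up (2 adjusted over the list alone, fry adjusted p = 0.578). Phosphate limitation markers had 2 up and 1 down of 7 (the same adjusted over the list alone, fry adjusted p = 0.611); PHO84 read 924 on glucose array 1 and 37.9 or less on the other glucose arrays. Mating type genes had 1 up and 1 down of 6 (1 and 2 adjusted over the list alone, fry adjusted p = 0.951; median 0.19, mean -0.06).

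**Figure D2:**
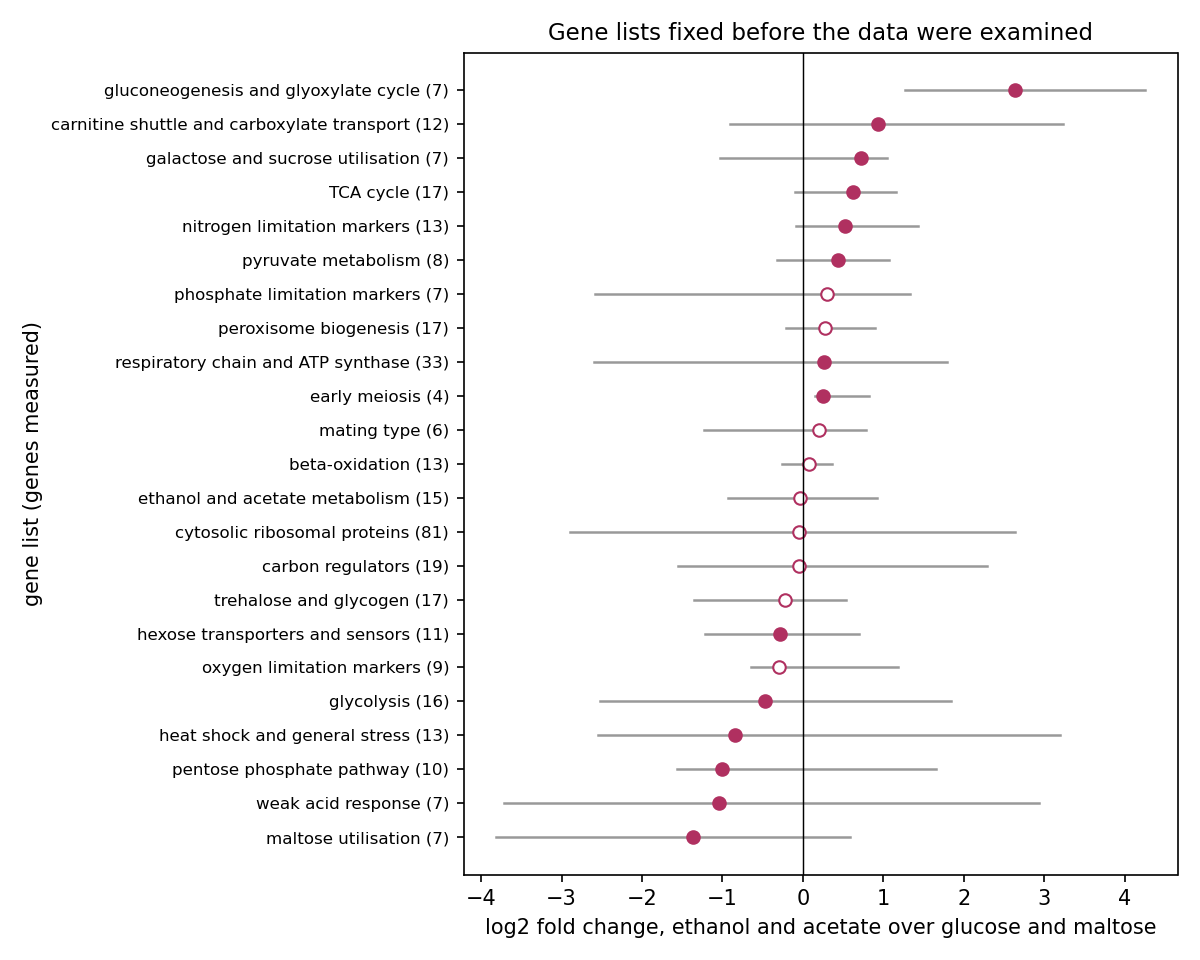
Log2 fold change of ethanol and acetate over glucose and maltose for the 23 gene lists; points are medians, lines run from the lowest to the highest gene, and filled points have a fry adjusted p under 0.05. Gluconeogenesis and glyoxylate cycle has the highest median (2.63) and maltose utilisation the lowest (-1.36).

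In this contrast limma called 1225 of 7176 probe sets, 817 higher and 408 lower on C2 compounds, and 404 of them changed at least 2-fold (256 higher, 148 lower). The median change over all probe sets was 0.12; it was 0.05 without maltose array 2, the array with the low median signal, and 0.01 after quantile normalization, which gave 775 higher and 637 lower calls. The count fell to 768 without ethanol array 3, 746 without acetate array 2 and 705 without acetate array 3. These are 3 of the 4 arrays with high actin ratios, and ethanol array 2 is the other. The number of calls was 147 with the 3'/5' covariate, and it also fell with only array 1 of both groups. Among arrays with code letter P it was 699 (375 higher, 324 lower), with the code letter as a block 568 (288 higher, 280 lower), and with array weights 2826. The F test across the 4 sources called 588 probe sets, 147 with the 3'/5' covariate and 99 with only array 1 of ethanol and of acetate. It was 294 without acetate array 2, 293 without acetate array 3, 1028 without maltose array 3, 314 among arrays with code letter P and 299 with the letter as a block.

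**Figure D3:**
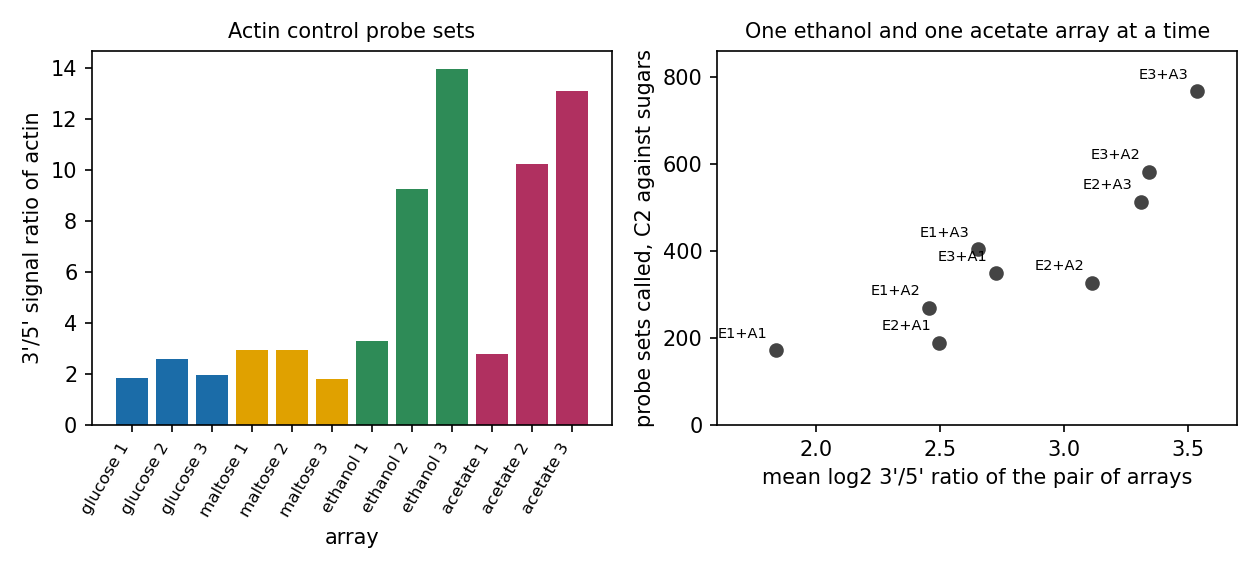
Left, actin 3'/5' signal ratio of the 12 arrays; right, probe sets called between C2 compounds and sugars with 1 ethanol (E) and 1 acetate (A) array at a time, against the mean log2 3'/5' ratio of the pair over actin and YER148W. Calls run from 172 for E1+A1 to 768 for E3+A3.

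The C2 response was compared in pairs of contrasts that share no array, though ethanol arrays 2 and 3 and acetate arrays 2 and 3 share a high 3'/5' ratio. The contrasts of a pair also share the estimate of the spread of each probe set. The numbers for independent calls are therefore not a strict reference. Ethanol against glucose and acetate against maltose shared 122 calls of the same sign, 81 higher and 41 lower, where independent calls would give 9.30 and 2.14, and 0 calls of opposite sign by limma. Ethanol against maltose and acetate against glucose shared 160, 98 higher and 62 lower, where 10.5 and 2.85 would be given, and 0 of opposite sign. Across probe sets, which are not independent replicates, the changes correlated with r = 0.62 and r = 0.59. The counts were 38 and 48 with the 3'/5' ratio as a covariate, 24 and 27 with only array 1 of ethanol and of acetate, and 63 and 72 among arrays with code letter P. The first was 63, 67, 79 and 61 without ethanol 2, ethanol 3, acetate 2 and glucose 3; the second was 91, 103, 78, 84 and 85 without ethanol 2, ethanol 3, acetate 2, acetate 3 and glucose 3.

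Ethanol and acetate cultures differed in 2 called genes. CDA2, a chitin deacetylase gene of the spore wall, was 4.07-fold higher on ethanol (log2 2.03 ± 0.26, 3 arrays against 3, limma adjusted p = 0.0046; signals 149 ± 16.5 and 36.6 ± 2.53, SD). SIT1, encoding a transporter of iron siderophores, was 5.75-fold higher on acetate (log2 -2.52 ± 0.34 for ethanol over acetate, adjusted p = 0.0046; signals 88.4 ± 12.8 and 517 ± 130). PCK1 (log2 0.05 ± 0.23), ICL1 (0.06 ± 0.20), ACS1 (0.08 ± 0.20) and ADH2 (0.03 ± 0.29) showed no called difference. Of the 23 lists 0 passed by fry. There were 308 probe sets with an unadjusted p under 0.05, and all 6 arrays carried code letter P. SIT1 lost its call without ethanol array 3 or acetate array 3 (adjusted p between 0.0512 and 0.0847), which left 1 call each, 4 calls were made without acetate array 1, and array weights gave 479.

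Maltose and glucose cultures, which separate a disaccharide from its monosaccharide, differed in sugar transport and cleavage. MAL31 rose 12.2-fold in maltose cultures (log2 3.61 ± 0.24, 3 arrays against 3, limma adjusted p = 7.61e-07; signals 2086 ± 502 and 169 ± 25.2, SD) and MAL11 rose 6.90-fold (log2 2.79 ± 0.24; signals 3458 ± 942 and 494 ± 86.5). The isomaltase gene IMA1 rose 10.7-fold, and YHR210C, an epimerase-like gene, rose 6.99-fold. Invertase SUC2 fell 3.60-fold and 3.12-fold on its 2 probe sets, and the transporter genes HXT4 and HXT10 fell 3.94-fold and 2.38-fold. INO1, the inositol-3-phosphate synthase gene, fell 2.14-fold (log2 -1.10 ± 0.20) and OPI3, a phosphatidylcholine synthesis gene, fell 2.12-fold (log2 -1.08 ± 0.20). PCK1 (log2 -0.26 ± 0.23), FBP1 (-0.33 ± 0.23), HXK1 (-0.66 ± 0.25), HXK2 (-0.37 ± 0.26) and ADH2 (0.97 ± 0.29) had no called difference.

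In this pair 4 of 7 maltose utilisation genes rose (4 adjusted over the list alone, fry adjusted p = 2.75e-05, and adjusted p = 0.0111 with an estimated correlation). Hexose transporters had 1 up and 2 down of 11 (the same adjusted over the list alone, fry adjusted p = 0.0193, and adjusted p = 0.709 with an estimated correlation). Galactose and sucrose genes had 1 down of 7 (2 adjusted over the list alone, fry adjusted p = 0.0169, and adjusted p = 0.509 with an estimated correlation). Both of these lists lost their call without maltose array 2 or glucose array 3, and the hexose transporters also without maltose array 1. Both also lost it with the code letter as a block, among arrays with code letter P, without glucose arrays 1 and 3 and with only array 1 of ethanol and of acetate (adjusted p up to 0.806 and 0.28 over their alternatives). The other 20 lists did not pass; heat shock and general stress had 6 of 13 up adjusted over the list alone and 0 over all genes (fry adjusted p = 0.0521).

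**Figure D4:**
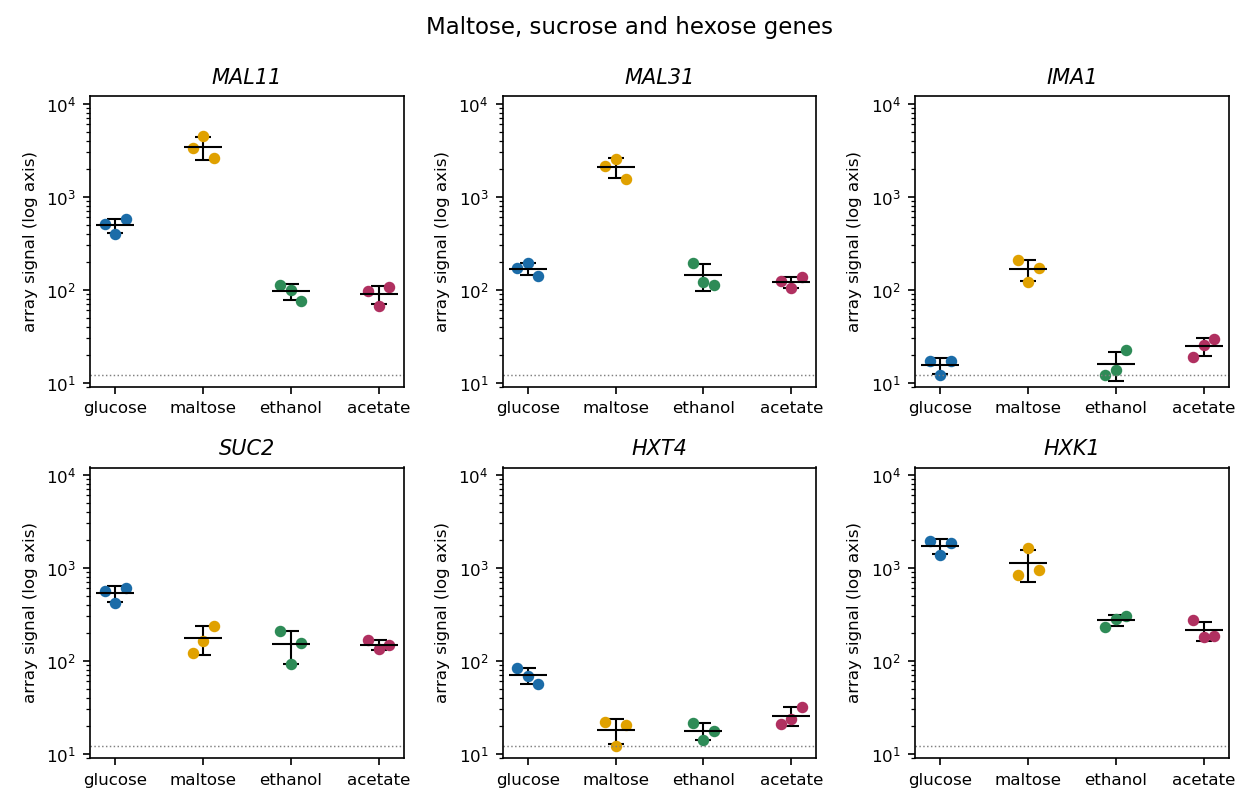
Array signals (log axis) of MAL11, MAL31, IMA1, SUC2, HXT4 and HXK1 for the 4 carbon sources; points are the 3 arrays, lines the mean and SD, and the dotted line the floor of 12. MAL11, MAL31 and IMA1 are highest on the 3 maltose arrays, and SUC2 and HXT4 on the 3 glucose arrays.

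Limma called 15 probe sets between maltose and glucose, 9 higher and 6 lower in maltose cultures, with 831 at an unadjusted p under 0.05; quantile normalization gave 13 higher and 4 lower. The median change over all probe sets was -0.20, and -0.03 after quantile normalization and also without maltose array 2 alone (-0.24 without maltose array 1, -0.31 without maltose array 3). The count was 8 without maltose array 1, 138 without maltose array 3, 9 without glucose array 1 and 31 without glucose array 2; among arrays with code letter P it was 40 (37 higher, 3 lower) and with the letter as a block 35 (32 higher, 3 lower). It was 2 with only array 1 of ethanol and of acetate, where fewer arrays estimate the spread. With the letter as a block INO1, OPI3, HXT4, HXT8, IMA5 and the weaker SUC2 probe set lost their calls (adjusted p between 0.0766 and 0.314). Among arrays with code letter P INO1, OPI3, HXT4, HXT8 and both SUC2 probe sets did (between 0.0591 and 0.296). Both letter settings rest on maltose array 3 and glucose arrays 1 and 3, so they are not separate checks. INO1 also lost its call with the replicate number as a block (adjusted p = 0.0555). IMA5, which was higher in maltose cultures, lost its call on leaving out any of 10 single arrays (adjusted p between 0.0757 and 0.222), and HXT8 without maltose 1, glucose 1 or glucose 2 (adjusted p between 0.0511 and 0.0982). INO1, OPI3, HXT10 and the weaker SUC2 probe set lost their calls on leaving out any of 7, 6, 4 and 6 single arrays (adjusted p up to 0.224, 0.095, 0.115 and 0.185), and HXT4 on leaving out glucose array 1 (adjusted p = 0.072).

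Ethanol against glucose cultures showed the C2 pattern with 1 sugar. PCK1 rose 17.7-fold (log2 4.15 ± 0.23, adjusted p = 2.87e-08), FBP1 9.91-fold (log2 3.31 ± 0.23), YAT1 9.23-fold (log2 3.21 ± 0.32), MLS1 8.87-fold (log2 3.15 ± 0.26) and CDA2 by log2 3.59 ± 0.26. FDH1 fell 45.1-fold on 1 of its probe sets (log2 -5.50 ± 0.57), PDR12 14.0-fold, HXK1 6.33-fold and MAL11 5.16-fold. All 7 genes of gluconeogenesis and the glyoxylate cycle rose (7 adjusted over the list alone, fry adjusted p = 3.27e-06, and adjusted p = 0.0111 with an estimated correlation), and 5 of 17 TCA cycle genes did (11 adjusted over the list alone, fry adjusted p = 0.000478, and adjusted p = 0.0495 with an estimated correlation). With only array 1 of ethanol and of acetate the TCA cycle list lost its fry call (adjusted p = 0.0809). Limma called 183 probe sets, 119 higher and 64 lower, of which 142 changed at least 2-fold. The count was 75 without ethanol array 2, 82 without ethanol array 3, 84 without glucose array 3 and 57 without glucose arrays 1 and 3. It was 40 with the 3'/5' covariate, 55 with only array 1 of ethanol and of acetate, and 239 among arrays with code letter P (193 with the letter as a block). SSA1, TDH3 and YDR524C-B were called higher, with differences that rested on glucose arrays 1 and 3; they lost the call without either of these, among other single arrays.

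Acetate against glucose cultures gave a like set. PCK1 rose 17.1-fold (log2 4.10 ± 0.23, adjusted p = 3.45e-08), MLS1 8.34-fold (log2 3.06 ± 0.26), FBP1 8.25-fold (log2 3.04 ± 0.23), YAT1 6.97-fold and CRC1 5.83-fold (log2 2.54 ± 0.22). FDH1 fell 38.9-fold (log2 -5.28 ± 0.57), PDR12 15.5-fold (log2 -3.96 ± 0.36), HXK1 8.17-fold (log2 -3.03 ± 0.25) and MAL11 5.55-fold; CYC7 was at least 7.60-fold lower, since all acetate arrays were at the floor. All 7 gluconeogenesis and glyoxylate genes rose (7 adjusted over the list alone, fry adjusted p = 3.64e-06, and adjusted p = 0.0111 with an estimated correlation), 8 of 17 TCA cycle genes rose (13 adjusted over the list alone, fry adjusted p = 8.36e-05, and adjusted p = 0.0294 with an estimated correlation), and 6 of 10 pentose phosphate genes fell with 1 up (7 and 1 adjusted over the list alone, fry adjusted p = 0.000869, and adjusted p = 0.0512 with an estimated correlation). With only array 1 of ethanol and of acetate the TCA cycle and pentose phosphate pathway lists lost their fry calls (adjusted p = 0.0533 and adjusted p = 0.101). Limma called 395 probe sets, 249 higher and 146 lower, of which 294 changed at least 2-fold. The count was 674 without acetate array 1, 133 without acetate array 2, 122 without acetate array 3, and 242, 217 and 159 without glucose arrays 1, 2 and 3. It was 62 with the 3'/5' covariate, 73 with only array 1 of ethanol and of acetate, 349 among arrays with code letter P and 317 with the letter as a block. RPS26A, SSA1, TDH3 and YDR524C-B rested on glucose arrays 1 and 3 here too and lost the call without either of these, among other single arrays.

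Ethanol against maltose cultures combined the C2 rise with the loss of maltose gene transcripts. PCK1 rose 21.3-fold (log2 4.41 ± 0.23, adjusted p = 5.65e-09), YAT1 12.7-fold (log2 3.67 ± 0.32) and FBP1 12.5-fold (log2 3.64 ± 0.23); CDA2 was at least 12.4-fold higher, since all maltose arrays were at the floor. MAL11 fell 35.6-fold (log2 -5.15 ± 0.24, adjusted p = 3.54e-09), MAL31 14.8-fold (log2 -3.88 ± 0.24) and IMA1 10.5-fold (log2 -3.39 ± 0.34). All 7 gluconeogenesis and glyoxylate genes rose (7 adjusted over the list alone, fry adjusted p = 3.27e-06, and adjusted p = 0.022 with an estimated correlation), and 4 of 7 maltose utilisation genes fell (4 adjusted over the list alone, fry adjusted p = 6.74e-06, and adjusted p = 0.0111 with an estimated correlation). Limma called 444 probe sets, 304 higher and 140 lower; quantile normalization gave 247 and 196 and moved the median change from 0.21 to 0.03, and it was 0.06 without maltose array 2 and 0.31 without maltose array 3. The count was 160 without ethanol array 2, 191 without ethanol array 3 and 989 without maltose array 3, and 130 with only the 6 arrays compared. With the 3'/5' covariate it was 160 and with only array 1 of ethanol and of acetate 73. It was 173 among arrays with code letter P (80 higher, 93 lower) and 160 with the letter as a block (62 higher, 98 lower), where lower calls outnumbered higher ones.

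Acetate against maltose cultures also combined the C2 rise with low maltose gene transcripts. PCK1 rose 20.5-fold (log2 4.36 ± 0.23, adjusted p = 6.73e-09), TPO2 12.5-fold (log2 3.65 ± 0.39), FBP1 10.4-fold (log2 3.38 ± 0.23) and CIT2 7.67-fold (log2 2.94 ± 0.33). MAL11 fell 38.3-fold (log2 -5.26 ± 0.24, adjusted p = 2.58e-09), MAL31 16.9-fold, FDH1 20.4-fold and 12.8-fold on its probe sets, and PDR12 12.3-fold; IMA5, another isomaltase gene, was at least 9.65-fold lower. All 7 gluconeogenesis and glyoxylate genes rose (7 adjusted over the list alone, fry adjusted p = 3.27e-06, and adjusted p = 0.0237 with an estimated correlation), and 9 of 13 heat shock and general stress genes fell (9 adjusted over the list alone, fry adjusted p = 0.00123, and adjusted p = 0.0512 with an estimated correlation). The heat shock and general stress list lost its fry call with only array 1 of ethanol and of acetate (adjusted p = 0.0817). Limma called 801 probe sets, 561 higher and 240 lower; quantile normalization gave 417 and 356 and moved the median change from 0.23 to 0.04, and it was 0.09 without maltose array 2. The count was 292 without acetate array 2, 250 without acetate array 3, 464 without maltose array 2 and 1342 without maltose array 3. It was 267 with the 3'/5' covariate and 94 with only array 1 of ethanol and of acetate. It was 195 among arrays with code letter P (74 higher, 121 lower) and 204 with the letter as a block (64 higher, 140 lower), where lower calls outnumbered higher ones.

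By limma few probe sets met the rule for 1 source, which needs a call against each of the other 3. The simulation of maltose against glucose recovered 50.7% of 2-fold changes in that 1 pair, so low counts may also come from missed changes. Array weights gave higher counts. CDA2 was the only probe set specific to ethanol and SIT1 the only one specific to acetate by limma, both higher there. Maltose cultures had 9 probe sets higher, those of MAL31, MAL11, IMA1, YHR210C, IMA5 and HXT8 and 3 without a gene name, and 2 lower, INO1 and OPI3; HXT8 was named after its value was seen, and the calls of IMA5, HXT8, INO1, OPI3, HXT10, HXT4 and 1 SUC2 probe set between maltose and glucose each ended without at least 1 single array. Glucose cultures had 4 probe sets higher, 2 of SUC2 and those of HXT4 and HXT10. Without maltose array 1 the maltose count was 6, without maltose array 3 it was 70 and without glucose array 1 it was 7. The glucose count was 18 without glucose array 2, 14 without maltose array 3, and 2 without acetate 2, maltose 1, maltose 2, glucose 1 or glucose 3. The ethanol count was 2 without glucose array 2, and the acetate count was 3 without acetate array 1, 2 without maltose array 2 or glucose array 1, and 0 without ethanol array 3 or acetate array 3. With only arrays of code letter P the ethanol, acetate, maltose and glucose counts were 1, 1, 30 and 7.

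Over all 7 contrasts 63 of the 161 list tests passed by fry, 34 up and 29 down, and 16 passed with an estimated correlation. Calls on different probe sets of a gene had opposite signs for NUP49 and YHB1 in the C2 contrast, and for NUP49 in acetate against maltose.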

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

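The tests of the 3'/5' ratio on the number and direction of calls and on the gluconeogenesis genes, of the compression and the ceiling of high signals, of maltose array 2, and of the share of higher calls with only array 1 were chosen only after the result was seen.

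The 3'/5' ratios of 2 control genes, 2 ribosomal RNA control probe sets and the ThrX spike, which no comparison used, were examined. In 20 cases they stood at more than 2 times the highest glucose array, or for the spike the highest array of the other sources. The actin 3'/5' ratio was 9.27 and 13.98 on ethanol arrays 2 and 3 and 10.2 and 13.1 on acetate arrays 2 and 3, against 2.60 at most on glucose arrays, and the YER148W ratio was 8.08, 10.05, 7.33 and 9.88 on the same arrays, against 3.01. An 18S ribosomal RNA control probe set read 667, 740 and 677 on maltose arrays 1 to 3, against 257 at most on glucose arrays. A 25S ribosomal RNA control probe set read 678 on ethanol array 1, 1414 on ethanol array 2, 169.6 on acetate array 1, and 472, 293 and 587 on maltose arrays 1 to 3, against 81.6 at most on glucose arrays. On glucose array 2 the 3', 5' and middle ThrX spike probe sets read 3647, 267.9 and 956, against 2.7, 11.2 and 7 at most on the arrays of the other sources.

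The first pattern is the number of probe sets called between C2 compounds and sugars, 1225. With 1 ethanol and 1 acetate array at a time the pair with the lowest 3'/5' ratios gave 172 calls and the pair with the highest gave 768, so RNA with a 3' bias may have raised the number. It cannot be the whole cause of the direction: of 1748 probe sets called without array 1 of both groups, glucose array 2 and maltose array 2, 73.9% had the same sign on these 4 arrays, where the mean log2 ratio differed by 0.07 and independent signs would give 51.3% (88.2% of the higher and 56.7% of the lower ones, with 71.6% of all probe sets higher; 73.0% to 88.2% over 9 choices of sugar arrays). Nor can it be the whole cause of the rise of gluconeogenesis and glyoxylate genes: 6 of 7 passed with only array 1, where CIT2 went from log2 2.63 ± 0.24 to 2.48 ± 0.48 (adjusted p = 0.0806 with 2 arrays in place of 6), and 7 of 7 passed with the ratio as a covariate. A share of the count that belongs to the carbon source stays open, since the 4 arrays with high ratios are all of ethanol and acetate.

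The second pattern is the low signal of bright probe sets on glucose arrays 1 and 3, whose highest signals were 3732 and 3765, with 0 probe sets above 4000 where the other arrays had 15 to 68. Over the 50 probe sets above 3000 on glucose array 2 the median log2 ratio of arrays 1 and 3 to array 2 was -0.60, with 46 lower on both, and over 289 probe sets between 1000 and 2000 it was 0.03. By the median of the other 9 arrays the ratio was -0.01 over 115 probe sets between 2000 and 3000, -0.21 over 34 up to 3732 and -0.62 over 40 above, so a gradual compression of high signals is a candidate explanation and a sharp ceiling stays undecided. TDH3, SSA1, RPS26A and YDR524C-B read 281 or less on both arrays, far below the highest signals there. Whether a compression or a ceiling of high signals can give such readings was not tested. The cause of their calls against glucose was not tested either. No biological explanation was tested, since the 3 arrays are replicates of 1 group.

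The third pattern is the direction of probe sets without a gene name, of which 303 were called higher and 19 lower on C2 compounds, against 514 and 389 with a name (247 and 32 against 528 and 605 after quantile normalization, which turned the balance of the named ones). On the 4 arrays with high 3'/5' ratios these probe sets lay above array 1 of both groups by 0.43 log2 more than named ones did, in 10 of 10 bins of signal, so the 3' bias may have added to their rise. Whether it is the whole cause of the share stays open: with only array 1 of both groups 59 of 61 calls were higher, 96.7%, but the mean log2 ratios of these arrays, 1.80 and 1.88, still lie above those of the glucose arrays, and with the ratio as a covariate 8 were higher and 6 lower, 57.1%, against 54.9% higher with a name. The low median signal of maltose array 2 was not the cause, since without it 91.1% were higher (522 and 473 with a name). A response to the carbon source was not told apart from the bias.

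Splits of the arrays were counted to ask whether chance can be excluded. It can for the calls among the 4 sources (real 588, highest of the other relabellings 271; 1 of 100 was as large) and for the C2 contrast (1225 against 86; 1 of 100). For the probe sets specific to maltose (11 against 1, with 1 of 100 as large) it is not claimed. Group names in a relabelling are arbitrary, and 2 of 100 had as many in any of the 4 groups, the real one included. The other of these 2 gave 83 in the group that carried the glucose name. For the single probe sets specific to acetate (1 against 0; 1 of 100) and to ethanol (1 against 1; 2 of 100) it is not claimed, since 5 of 100 had at least 1 in any group, the real one and 3 others with the 3 acetate arrays together included. The acetate count was 0 without ethanol array 3 or acetate array 3. For the probe sets specific to glucose (4, with 2 of 100 as large) it is not claimed either, since the highest other relabelling gave 83. That relabelling, which also gave the 271, put ethanol array 3 and acetate arrays 2 and 3 in 1 group, the 3 arrays with the highest actin ratios, and points to a structure of the arrays.

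For the 6 pairs the 10 splits are too few for a share under 0.05. Ethanol against acetate gave 2 calls and the highest other split 65, so 2 of 10 were as large; that split set acetate array 1 and ethanol arrays 1 and 2, with the 3 lowest actin ratios, against the 3 highest, and with the ratio as a covariate the count was 2. The real and highest other counts were 15 and 1 for maltose against glucose, 183 and 0 for ethanol against glucose, 395 and 0 for acetate against glucose, 444 and 1 for ethanol against maltose, and 801 and 0 for acetate against maltose, with 1 of 10 as large in each.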

How the results depend on the processing

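The settings with the 3'/5' ratio, with only array 1 of ethanol and of acetate, without glucose arrays 1 and 3 and without bright probe sets were chosen only after seeing the data. Of the named C2 calls, 20 of 86 held under all alternatives, as did 9 of 67 for acetate against maltose, 9 of 65 for ethanol against maltose, 7 of 50 for ethanol against glucose, 4 of 60 for acetate against glucose, 1 of 2 for ethanol against acetate (CDA2) and 0 of 12 for maltose against glucose; none of these named calls reversed its sign. PCK1, FBP1, CRC1 and ICL1 held in the C2 contrast and its 4 pairs. Signal over background limits dim probe sets; 2099 never entered. Where no reason is given below, the cause was not tested.

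Counts are given in the order F test, C2 contrast, ethanol with acetate, maltose with glucose, ethanol with glucose, acetate with glucose, ethanol with maltose, acetate with maltose. Counts that moved by over 1.5 times with array weights were 3375, 2826, 479, 446, 1111, 2598, 1538 and 2597; source-specific counts were 55 for ethanol, 233 acetate, 206 maltose and 88 glucose, and same-sign counts of the independent pairs 662 and 759. With the replicate number as a block the counts were 723, 1298, 2, 15, 203, 496, 483 and 872. Across the sources the numbers did not pair the cultures as a rule. Of 18 same-numbered pairs, 6 had residual correlations above 0.1 (range -0.21 to 0.53), and the own number was best in 6. Ethanol with acetate was an exception for numbers 1 and 3 (r = 0.53 and 0.43, each best with its own number), not for number 2 (-0.08). Ethanol array 1 also correlated more with acetate array 1 (r = 0.982) than with ethanol arrays 2 and 3 (0.973 and 0.954). The ethanol and acetate arrays may therefore not be independent units, which the p-values of the C2 contrast assume. With the code letter as a block the F test gave 299, the C2 contrast 568, maltose with glucose 35, ethanol with maltose 160, acetate with maltose 204, maltose-specific 25, glucose-specific 7, and the independent pairs 66 and 64. With only code letter P, which leaves 1 maltose array assumed to vary like the other groups, they were 314, 699, 40, 173, 195, 30, 7, 63 and 72. Without a filter the F test gave 285, the C2 contrast 789, ethanol with glucose 107, acetate with glucose 182, ethanol with maltose 272, acetate with maltose 503 and the second independent pair 92. A mean signal of at least 100, with fewer probe sets, gave 761 for the C2 contrast, 1 for ethanol with acetate, 8 for maltose with glucose, 518 for acetate with maltose, and 0, 6 and 2 specific to ethanol, maltose and glucose by limma. In that setting galactose and sucrose utilisation turned to down in the C2 contrast (adjusted p = 0.00864; 0.139 at most over the alternatives), ethanol with maltose (0.613, the highest) and acetate with maltose (0.700, the highest). A fold minimum of 2 left 404 in the C2 contrast. Only the 6 arrays compared, with fewer arrays, gave 2 for maltose with glucose, 130 for ethanol with maltose and 287 for acetate with maltose. Quantile normalization gave 2 specific to glucose. The C2 contrast was 686 without the glucose and 748 without the maltose arrays. Camera with an estimated correlation passed 16 of 161 list tests against 63 by fry.

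The 3'/5' covariate gave 147 for the F test, 147 for the C2 contrast, 40 for ethanol with glucose, 62 for acetate with glucose, 160 for ethanol with maltose, 267 for acetate with maltose, 0 specific to glucose by limma, 38 and 48 for the independent pairs, and 38 list tests. Only array 1 of ethanol and of acetate, a lone array in each group assumed to vary like the others, gave 99, 172, 23, 2, 55, 73, 73 and 94 in the order above, 7, 16, 2 and 0 specific to ethanol, acetate, maltose and glucose, 24 and 27 for the independent pairs and 15 list tests. The same without maltose array 2 gave 67, 145, 11, 0, 34, 63, 36 and 71, then 4, 7, 0 and 0, then 17 and 16, and 15 list tests. Without glucose arrays 1 and 3 the F test gave 301, the C2 contrast 478, maltose with glucose 7, ethanol with glucose 57, acetate with glucose 92, ethanol with maltose 276, acetate with maltose 486, maltose-specific 6, glucose-specific 1, and the independent pairs 43 and 55. Without probe sets above 2000 ethanol with glucose gave 115.

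Leaving out 1 array at a time gave 293 to 1028 for the F test, 705 to 1524 for the C2 contrast, 1 to 4 for ethanol with acetate, 8 to 138 for maltose with glucose, 75 to 243 for ethanol with glucose, 122 to 674 for acetate with glucose, 160 to 989 for ethanol with maltose and 250 to 1342 for acetate with maltose. Source-specific counts were 1 to 2 for ethanol, 0 to 3 acetate, 6 to 70 maltose and 2 to 18 glucose; the independent pairs gave 61 to 149 and 78 to 225, and 56 to 72 list tests passed.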

Other observations

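The 3 list tests in this part were written before their results were seen, but their lists were chosen only after the values of SIT1, INO1, OPI3 and COX1 had been seen, and the rule that leaves a list with fewer than 3 measured genes undecided was added after the result was seen. Each of these tests was written for a single contrast. The other contrasts of the lists, such as acetate against glucose for iron uptake, had no prediction.

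Genes of iron uptake were higher on acetate than on ethanol as a group. Of 15 measured genes, SIT1 left out, 13 were lower in ethanol than in acetate cultures, with a median log2 change of -0.55. The fry test of limma gave an unadjusted p of 0.000651, or adjusted p = 0.00683 over the 21 tests of this part (0.0101 with the 3'/5' ratio as a covariate). In acetate against glucose cultures 15 of 15 were higher (median 0.76, adjusted p = 0.00683), and in ethanol against glucose cultures 10 of 15 were (median 0.20, adjusted p = 0.555). Against maltose 13 were higher and 2 lower on acetate (median 0.51, fry adjusted p = 0.0221). On ethanol 8 were higher and 7 lower than in maltose cultures (median 0.05, fry adjusted p = 0.596). By limma 0 of the 15 genes were called between ethanol and acetate, where 308 of all probe sets had an unadjusted p under 0.05. The rise of SIT1 on acetate may be part of a wider response of iron uptake genes, a hypothesis found on the same data.

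Phospholipid synthesis genes that respond to inositol showed a smaller shift between the sugars. Of 13 genes, INO1 and OPI3 left out, 10 were lower in maltose than in glucose cultures, with a median log2 change of -0.22. The unadjusted fry p was 0.0106 and adjusted p = 0.028 (0.0927 with the covariate, which is not under 0.05), and limma called 0 of them, where 831 of all probe sets had an unadjusted p under 0.05. The median of all probe sets in this contrast was -0.20, close to that of the list, so a shift of the whole array could add to it. Without maltose array 2 the medians were -0.03 for all probe sets and -0.16 for the list, with adjusted p = 0.0588.

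COX1, a mitochondrially encoded gene, was higher on C2 compounds (log2 1.92 ± 0.28, adjusted p = 0.000334), and the other genes of the mitochondrial genome were to be tested as a list. Only OLI1 of the 7 was measured (log2 0.90, unadjusted fry p of 0.00155, adjusted p = 0.0109, or 0.23 with the covariate), so the test could not decide.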
